A study of Homo sapiens with 10 samples.

How the data were processed

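Single-cell RNA sequencing with droplet 3' chemistry was applied to H1 cells and to steps of their differentiation into artery and vein endothelial cells (ECs). The deposited values used here are counts of unique molecular identifiers (UMIs) per gene and cell barcode, in filtered matrices. They were made with Cell Ranger 9.0.1 on the human builds hg38 and GRCh38, per the submitters' processing notes. Whether intronic reads were counted, and which annotation release was used, is not given in the sources used here. The artery EC matrices hold 33538 genes and the other matrices 38606, and 32498 genes are shared by Ensembl identifier. The shared genes held from 98.5% of the UMIs in primitive streak to 99.6% in the unsorted artery ECs, and all levels refer to them. Samples were grouped by differentiation step and sorting, as the labels give them. Of the 10 samples, those of hPSCs (6912 barcodes over both samples), sorted primed ECs (6313 barcodes) and sorted vein ECs (6583 barcodes) have count matrices that were not analysed here. The labels do not say whether libraries share a culture or a day.

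Barcodes were kept with at least 1000 genes detected and at most 20% mitochondrial UMIs. This left out 10.1% of barcodes in primitive streak, 9.59% in lateral mesoderm, 2.79% in sorted and 20.1% in unsorted artery ECs, 8.84% in primed ECs and 22.4% in vein ECs. Doublet scores were the share of simulated doublets among each barcode's neighbours. The highest scores were removed at an assumed rate of 0.8% per 1000 barcodes, which took out 41, 99, 184, 102, 55 and 200 barcodes in the same order of libraries. The rate was assumed and no doublet was observed directly. Each library was clustered on its own from log-normalised counts of 2000 variable genes, 30 principal components and 15 neighbours, with the Leiden algorithm at resolution 0.5. Cycling cells were left in. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, with seed 1.

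Marker lists for 11 cell classes were fixed before the data were examined, as were the gene lists, comparisons, filters, the rule for named genes and all alternatives except those named below as added. A cluster took the class with the highest mean of its markers, each scaled to its highest cluster and to at least 20 CPM. It stayed unnamed with fewer than 3 markers detected, or at a median depth below the library median divided by 3 with no own marker among its 10 leading genes. It also stayed unnamed when markers of other classes outnumbered its own among the leading genes against clusters of other names. This scoring and the set of clusters against which leading genes are judged were chosen after seeing the data, after thresholds on the score, on its ratio to the next class and on the share of detected markers had been tried. The rule left unnamed 64.8% of lateral mesoderm, 9.15% of primitive streak, 10.1% of unsorted artery EC, 1.39% of primed EC and 3.47% of vein EC cells. Judged within their library alone, endothelial-like clusters in all 4 EC libraries had a marker of another class among their 10 leading genes, and a comparison without them was added after seeing the data.

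For each of 7 comparisons UMIs were summed over the kept or endothelial-like cells of a library and scaled to CPM over a total of 1000000. Ratios were taken with a pseudocount of 1 CPM. With 1 library per group no test was made. Sums have exact 95% Poisson intervals and shares have exact 95% Clopper-Pearson intervals, which cover counting error only, and a count of 0 is set against a floor of 3 counts. Bootstrap intervals of medians over genes came from 2000 draws of those genes. They cover the spread among the genes, not counting error or differences between libraries. Named genes were the 10 with the highest and the 10 with the lowest ratio among genes with at least 50 CPM in the higher library. Genes known only by a clone or Ensembl name, LINC and antisense names, mitochondrial and ribosomal protein genes, pseudogenes by name and sex-linked marker genes were left out of that rule. The names alone were used, so that other noncoding RNAs such as HPAT5 stayed in. In primed against artery ECs, 1 gene that the rule names is not reported here. SOX17, APLNR, NR2F2, CDH5 and PECAM1 were read in every library.

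The 26 gene lists were pluripotency, primitive streak, lateral mesoderm, paraxial mesoderm, endothelial, artery, vein, ERK response, angiogenic tip, Notch targets, BMP targets, TGF-beta targets, Wnt targets, S phase, G2/M, blood, mural and mesenchymal, cardiac, endoderm, epithelial and amnion, neural, early response and stress, hypoxia, glycolysis, cholesterol synthesis, and extracellular matrix. A member was measured at 5 CPM or more in either library. A list with at least 3 measured members was described by its median log2 ratio and the percentile of that median among 10000 random lists matched on mean expression. It stands apart outside percentiles 2.5 to 97.5. Up to 4 members with the largest ratios serve as examples. The endoderm list never had 3 measured members, and the neural list only in lateral mesoderm against primitive streak. There are 9 genes in more than 1 list: HEY1, HEY2, HES4, DLL4, CXCR4, CD34, SMAD7, SP5 and TAGLN. Coordinates are from GENCODE 29 on GRCh38.

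Shares of cells with SOX17 and APLNR were taken after thinning each cell to 10000 UMIs, a depth chosen after seeing the libraries, and shallower cells were left out. Alternatives were no filter on cells, a stricter filter (2000 genes, 10% mitochondrial UMIs), no doublet removal, and Leiden resolution 1. Others were scaling by TMM (edgeR 4.0.16 in R 4.3.3) or by the median of ratios (DESeq2 1.42.0), the mean over cells of CPM, a pseudocount of 10 CPM, and no filter on low members. A further alternative left out genes at least 4-fold apart between both artery libraries and each of the other 4. For endothelial-like cells, a rule of at least 3 endothelial markers per thinned cell and the use of all kept cells were tried, and for the shares with both genes no thinning and at least 2 UMIs of each. Alternatives used 2000 random lists. Added after seeing the data were the comparison without clusters led by another class and the sorted comparison in endothelial-like cells only. On data simulated from vein against primed ECs, with 11524 genes run, 98% of 100 genes changed 2-fold and 90% of 100 genes changed 4-fold came within 0.25 log2 units of the truth. None of 11324 unchanged genes reached 2-fold, 5.2% of 500 random lists fell outside the central 95%, and a list raised 2-fold had a median of 0.97 at percentile 100. The simulated counts were Poisson draws from the averaged profile of both libraries. They held no variation between libraries or cells and no correlation among genes, so these rates cover counting error only.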

Results

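Gene expression was measured by droplet-based single-cell RNA sequencing along a stepwise differentiation of H1 cells, an established human embryonic stem cell line, into artery and vein endothelial cells (ECs). H1 cells are human pluripotent stem cells (hPSCs), which can form every embryonic germ layer. The protocol passed through primitive streak at day 1 and lateral mesoderm at day 2. From there an artery branch gave artery ECs at day 3, and a vein branch gave primed ECs at day 3 and vein ECs at day 4. Each step took 24 hours in a defined serum-free medium. The 10 samples fall into 9 groups. The count matrices of 6 groups were analysed, with 1 library per group. Each of the 5 cell states after pluripotency was represented by an unsorted library. Artery ECs were also represented by a library sorted for CD144, the cell-surface cadherin encoded by CDH5. Because each group was 1 library, no difference below has a replicate check, and no test between groups was made. Intervals of levels and shares cover counting error only, and bootstrap intervals cover only the spread among the genes resampled.

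The unsorted primitive streak library held 2392 barcodes and 201102792 unique molecular identifiers (UMIs), and the lateral mesoderm library held 3701 barcodes and 191290899 UMIs. The sorted artery EC library held 4869 barcodes and 128557458 UMIs, and the unsorted artery EC library held 3985 barcodes and 131542550 UMIs. The primed EC library held 2750 barcodes and 175574488 UMIs, and the vein EC library held 5678 barcodes and 202503870 UMIs. After filtering, 2110 primitive streak, 3247 lateral mesoderm, 4549 sorted artery EC, 3083 unsorted artery EC, 2452 primed EC and 4208 vein EC cells were kept. Their median depth ranged from 21585 UMIs per cell in sorted artery ECs to 90687 in primitive streak. Levels are given in CPM, the counts of a gene per 1000000 UMIs summed over the kept cells and the 32498 genes in both gene lists used for counting. Folds are ratios of (CPM + 1), which understate differences of low genes. The 95% Poisson interval of a gene named for its fold lay within 2.47% of its level in the higher library, a bound set by PLEKHA7.

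Before the branches were compared, 5 genes were read in every library: SOX17, a transcription factor of arterial endothelium, the vein-associated genes APLNR (the apelin receptor) and NR2F2 (the transcription factor COUP-TFII), and the endothelial junction genes CDH5 and PECAM1. SOX17 (ENSG00000164736) was at 0.19 CPM in primitive streak, 18.4 in lateral mesoderm, 476 in sorted artery ECs, 459 in unsorted artery ECs, 229 in primed ECs and 16.5 in vein ECs. APLNR (ENSG00000134817) was at 33.3 CPM in primitive streak, 196 in lateral mesoderm, 2.87 in sorted and 8.95 in unsorted artery ECs, 140.0 in primed ECs and 235 in vein ECs. NR2F2 (ENSG00000185551) was at 0.158, 11.4, 0.305, 1.91, 16.7 and 291 CPM in the same order of libraries. CDH5 (ENSG00000179776) had 1 UMI in the whole primitive streak library, which is 0.00528 CPM with a Poisson interval of 0.000134 to 0.0294. It was at 21.3 CPM in lateral mesoderm, 485 in unsorted artery ECs, 229 in primed ECs and 203 in vein ECs. PECAM1 (ENSG00000261371) was at 0.0792 CPM in primitive streak, 11.0 in lateral mesoderm, 346 in sorted and 302 in unsorted artery ECs, 153 in primed ECs and 182 in vein ECs. In the GENCODE 29 annotation of GRCh38, SOX17 lies on chromosome 8 at 54457935 to 54460888 (plus strand) and APLNR on chromosome 11 at 57233577 to 57237314 (minus strand). NR2F2 lies on chromosome 15 at 96325938 to 96340263 (plus strand), CDH5 on chromosome 16 at 66366622 to 66404786 (plus strand) and PECAM1 on chromosome 17 at 64319415 to 64413776 (minus strand). All 5 are protein-coding genes.

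**Figure D1:**
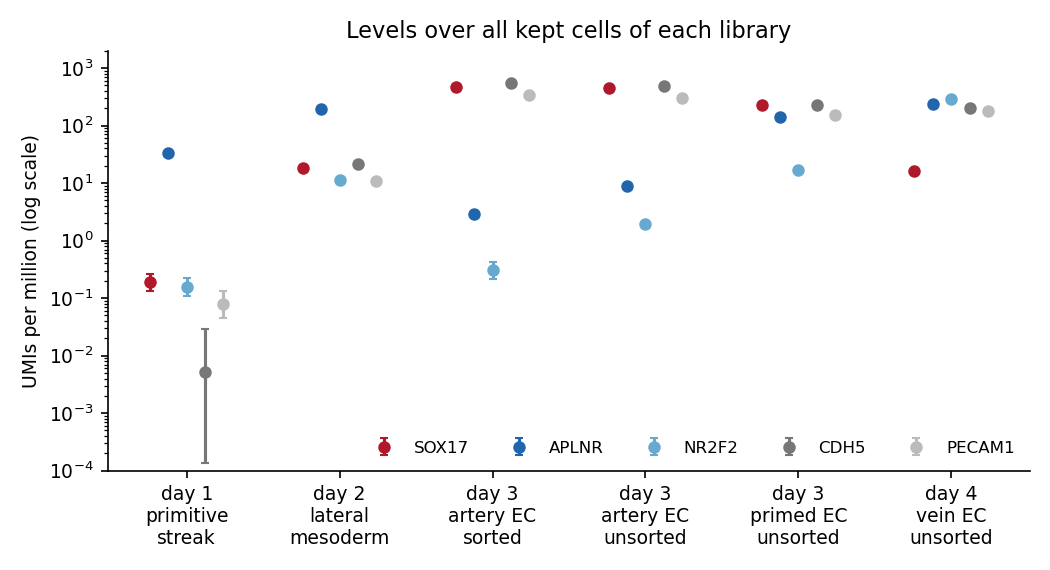
Levels of SOX17, APLNR, NR2F2, CDH5 and PECAM1 over all kept cells of each library, in CPM on a log axis, 1 point per library, with bars for the exact 95% Poisson interval (counting error only, smaller than the point where not visible). SOX17 was at 459 CPM in unsorted artery ECs and 16.5 in vein ECs, NR2F2 was at 1.91 and 291 CPM, and primed ECs held both SOX17 (229 CPM) and APLNR (140.0 CPM).

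The first comparison, lateral mesoderm against primitive streak, asked what distinguished these consecutive steps. Genes of the primitive streak were far lower in lateral mesoderm, and genes of the endothelial program were already higher. MIXL1, a streak homeobox gene, was at 1.34 CPM in lateral mesoderm against 1075 in primitive streak (460-fold lower), and TBXT (brachyury) was at 1.04 against 428 CPM (210.5-fold lower). The NODAL ligand gene was 147-fold lower. In the other direction FLI1, an ETS transcription factor of endothelium and blood, was at 407 against 0.311 CPM (311-fold higher). ETV2, a master regulator of endothelial specification, was at 245 against 1.45 CPM (100.4-fold higher).

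Of 12 measured members of the primitive streak list, 11 were at least 2-fold lower and 1 was at least 2-fold higher, with a median log2 ratio of -4.94 (percentile 0 among 10000 random lists matched on mean expression, whose central 95% ran from -0.44 to 0.38). All 16 measured members of the endothelial list were at least 2-fold higher, with a median of 4.52 (percentile 100). SOX7 was at 132 against 0.702 CPM and TAL1 at 76.7 against 0.0211 CPM. All 11 measured Wnt target genes were at least 2-fold lower, with a median of -4.06, and the Wnt antagonist gene DKK1 was at 1.79 against 1178 CPM. The lateral mesoderm list was mixed, with 4 of 12 members at least 2-fold higher and 4 at least 2-fold lower (median 0.16, percentile 84.0). HAND2 was at 31.0 against 0.433 CPM and BMP4 at 153 against 29.2 CPM, while PDGFRA was at 4.86 against 28.3 CPM. Genes of paraxial mesoderm, the neighbouring mesodermal fate, were lower in lateral mesoderm (5 of 5 members, median -2.30), led by MSGN1 at 0.354 against 271 CPM. Pluripotency genes were also lower (6 of 9 at least 2-fold, median -1.28), with POU5F1 at 156 against 588 CPM and NANOG at 0.107 against 10.1 CPM. Epithelial genes were lower for 5 of 6 members (median -2.72), with the epithelial adhesion gene EPCAM at 16.6 against 221 CPM. ERK response genes had a median of 1.11, with 7 of 14 at least 2-fold higher, and DUSP6, an ERK phosphatase induced by ERK signalling, was at 335 against 29.5 CPM.

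Other genes named by their fold fell outside these lists or in several of them. Higher in lateral mesoderm were TFPI (592 against 5.05 CPM), PMP22 (382 against 3.70 CPM), PLCL1 (260 against 2.45 CPM), RCSD1 (156 against 0.797 CPM), and the homeobox genes HLX (105 against 0.153 CPM) and HHEX (97.6 against 0.0633 CPM). Lower were DKK4 (0.0618 against 204 CPM), TTC29 (1.38 against 339 CPM), CDX1 (1.38 against 157 CPM), HPAT5 (4.29 against 304 CPM) and ZIC2 (0.753 against 94.1 CPM). The vein list (median 1.77, 5 of 8 higher), artery list (0.85, 5 of 12 higher), angiogenic tip list (2.02, 6 of 9 higher), mural list (1.65, 5 of 8 higher) and extracellular matrix list (1.31, 5 of 9 higher) all lay above percentile 99. Not all members went this way, and CXCR4, of the artery and tip lists, was lower (3.69 against 16.1 CPM). BMP targets (0.91), cholesterol synthesis (0.62) and cardiac genes (1.34 over 3 members) lay above percentile 98. Notch targets (0.84, percentile 96.2) and G2/M genes (0.12, percentile 80.3) lay within the central 95% of random lists. TGF-beta targets (-1.25), hypoxia genes (-0.85) and S phase genes (-0.55) lay below percentile 1. Glycolysis (-0.12) and early response genes (-0.50) lay inside. The blood list (3.07) and the neural list (-2.55) rested on 3 members each. With no filter on low members, the blood list turned to -0.0030, the neural list moved to -0.02 and the hypoxia list to -0.44, all inside the random range. Another scaling of the libraries shifted all log2 ratios of this comparison by -0.13.

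The next comparison, unsorted artery ECs against lateral mesoderm, asked what marked the artery branch step. Genes of endothelium, arteries and angiogenic tip cells were higher in artery ECs, and genes of lateral mesoderm, BMP signalling and DNA replication were lower. ESM1 (endocan), a tip cell gene, was at 1581 against 0.0281 CPM (1538-fold higher). EDN1 (endothelin 1) was at 466 against 0.551 CPM, PDGFB at 225 against 1.60 CPM, and DLL4, an arterial Notch ligand, at 134 against 0.601 CPM. ETV2 was at 1.81 against 245 CPM (87.5-fold lower).

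In the endothelial list 13 of 18 members were at least 2-fold higher and 2 at least 2-fold lower, with a median of 2.68 (percentile 100). CD34 was at 448 against 6.01 CPM, ROBO4 at 96.9 against 1.46 CPM and PECAM1 at 302 against 11.0 CPM. In the artery list 15 of 17 members were at least 2-fold higher and none at least 2-fold lower (median 3.23, percentile 100). MECOM was at 1647 against 23.1 CPM and the chemokine receptor gene CXCR4 at 238 against 3.69 CPM. Notch targets (median 2.63, 5 of 6 higher) and angiogenic tip genes (3.09, 9 of 11 higher) went with them, and HEY1, a Notch target of arteries, was at 405 against 42.1 CPM. In the lateral mesoderm list 10 of 11 members were at least 2-fold lower (median -2.53, percentile 0), with MSX1 at 9.08 against 259 CPM and HAND1 at 20.1 against 130.1 CPM. BMP target genes were lower for 7 of 8 members (median -2.49), with ID2 at 38.9 against 454 CPM. S phase genes were lower for 11 of 12 members (median -1.67), with the ribonucleotide reductase gene RRM2 at 9.78 against 117 CPM, and G2/M genes for 8 of 12 (median -1.22). Glycolysis genes were lower for 8 of 9 (median -1.44), with LDHA at 40.1 against 243 CPM, and ERK response genes for 8 of 13 (median -1.15), with IER3 at 26.0 against 134 CPM. The vein list had a median of -0.45 (percentile 10.3), with APLNR at 8.95 against 196 CPM and STAB1 at 13.1 against 0.247 CPM.

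Further genes named by their fold were SORBS2 (565 against 0.646 CPM), FOXP2 (364 against 0.961 CPM), DCC (317 against 2.51 CPM), GALNT18 (286 against 2.14 CPM), ACSM3 (236 against 2.20 CPM) and METTL24 (90.3 against 0.264 CPM), all higher in artery ECs. Lower were TOMM6 (0 UMIs against 256 CPM, where 3 UMIs would be 0.0247 CPM), NME2 (5.81 against 1175 CPM), EEF1G (7.99 against 1146 CPM), HTR1F (0.329 against 109.8 CPM), ATP6V0C (0.412 against 95.3 CPM), CBS (0.807 against 121 CPM), MRPS24 (0.848 against 116 CPM) and B3GALT1 (1.54 against 156 CPM). G0S2 had 2 UMIs in artery ECs and 12488 in lateral mesoderm. Pluripotency (-1.05), Wnt target (-1.23), primitive streak (-3.29, 4 members) and blood (-2.46, 3 members) medians lay below percentile 1. The primitive streak and blood medians moved to -0.22 and -0.08 with no filter on low members. Paraxial mesoderm (-1.08), cardiac (-1.12), TGF-beta target (0.20), mural (-0.02), epithelial (-0.31), early response (-0.43), hypoxia (0.11) and cholesterol synthesis (0.33) medians lay within the central 95% of random lists. Extracellular matrix genes had a median of 1.22, with HSPG2 at 773 against 34.6 CPM.

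The artery libraries were counted on a list of 33538 genes and the others on 38606. The artery branch therefore cannot be told apart from a batch in any comparison with another library. Across the shared genes, 150 were at least 4-fold lower and 125 at least 4-fold higher in both artery libraries than in each of the other 4. Of the lower genes 75.3% had exons that overlapped another gene of the same strand, against 9.80% of genes of like expression, and of the higher genes 6.40% did, against 9.37%. Among the genes named above, TOMM6, NME2, EEF1G, ATP6V0C, MRPS24, CBS, HTR1F, B3GALT1, ESM1, SORBS2, EDN1, PDGFB, DLL4, MECOM, CXCR4, HSPG2, ACSM3 and METTL24 belong to these sets. The sets were picked by their distance from the artery libraries, so that leaving them out shrinks differences from artery ECs by construction. The extracellular matrix median was then 0.68, inside the random range. Another scaling shifted all log2 ratios of this comparison by 0.19 to 0.21.

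Primed ECs were compared with lateral mesoderm for the corresponding step of the vein branch. Endothelial genes were higher and mesodermal genes lower here too, with S phase and G2/M genes close to equal. ESM1 was at 101 against 0.0281 CPM (98.9-fold higher), TM4SF18 at 544 against 6.15 CPM (76.2-fold) and the endothelial surface genes CD93 and CD34 at 132 against 0.978 CPM and 379 against 6.01 CPM. HAS2, a hyaluronan synthase, was at 1.95 against 83.7 CPM (28.7-fold lower), ETV2 at 10.1 against 245 CPM, and the Notch and BMP responsive gene HES1 at 3.42 against 77.1 CPM.

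In the endothelial list 13 of 18 members were at least 2-fold higher and 2 at least 2-fold lower (median 2.53, percentile 100), with CLDN5 at 39.5 against 0.27 CPM. In the artery list 8 of 15 were at least 2-fold higher and 4 at least 2-fold lower (median 1.38, percentile 100), with JAG2 at 44.9 against 0.714 CPM and SOX17 at 229 against 18.4 CPM. In the vein list 4 of 10 were at least 2-fold higher and none at least 2-fold lower (median 0.32, percentile 90.8), with FLT4 at 68.3 against 8.53 CPM. Lateral mesoderm genes were lower for 9 of 11 members (median -1.71, percentile 0), with MSX1 at 22.9 against 259 CPM and TBX20 at 16.3 against 78.2 CPM. BMP targets (median -1.59, 6 of 8 lower), ERK response genes (-0.93, 7 of 14 lower and 1 higher) and Wnt targets (-1.22, 5 of 7 lower) were on the same side. S phase genes had a median of 0.19 and G2/M genes of -0.05, and none of either list was 2-fold apart.

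Other genes named by their fold were CHRM3 (285 against 5.87 CPM), INSYN2B (180.0 against 3.45 CPM), ADGRF5 (71.8 against 0.939 CPM), RFX8 (63.5 against 0.731 CPM), S100A4 (468 CPM, 36.2-fold) and S100A3 (52.0 against 0.59 CPM), all higher in primed ECs. GATM (3.45 against 65.6 CPM), LRFN5 (50.1 against 706 CPM), POU5F1 (11.0 against 156 CPM), BMPER (13.4 against 187 CPM), NRG3 (9.02 against 121 CPM) and NTS (183 against 2115 CPM) were lower. Angiogenic tip genes (1.73, 8 of 10 higher), cholesterol synthesis (0.54) and extracellular matrix genes (0.48) lay above percentile 98. Pluripotency (-1.69), primitive streak (-2.64), TGF-beta target (-1.04) and cardiac (-3.02) medians lay below percentile 1. Notch targets had a median of 1.38 over 5 members (percentile 99.9), which moved to 0.11 with no filter on low members. The members were mixed, since HES1, of this list, was lower (3.42 against 77.1 CPM). Blood (-0.18), epithelial (-0.15), early response (0.11), hypoxia (0.19) and glycolysis (-0.19) medians lay within the central 95% of random lists. The mural median (-0.38) lay at the edge of that range, at percentile 2.51. It was below the range with the stricter filter on cells (-0.39), with no doublet removal (-0.40) and with no filter on low members (-0.25). The paraxial mesoderm median (-0.89) lay inside the range, and was -0.41 and below it with no filter on low members.

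The share of cells in clusters called endothelial-like was estimated from the clusters of each library. The markers were fixed before the data were examined and scaled over the clusters of all libraries, and the scoring rule was settled after the data were seen. It was 84.2% in unsorted artery ECs (2595 of 3083 kept cells, exact 95% binomial interval 82.8 to 85.4), 78.2% in primed ECs (1917 of 2452, 76.5 to 79.8) and 79.3% in vein ECs (3339 of 4208, 78.1 to 80.6). All 4549 kept cells of the sorted artery library fell in such clusters, and none of 2110 primitive streak cells did (exact 95% upper limit 0.175%, counting error alone). A rule of at least 3 endothelial markers per cell gave 1.15% there. In lateral mesoderm 1142 of 3247 cells (35.2%, 33.5 to 36.8) were in such clusters, at CDH5 levels of 28.5 to 64.1 CPM per cluster. Of these, 505 cells were in a cluster led by histone genes such as H1-5, whose score was 0.211 for endothelial and 0.209 for lateral mesoderm markers. This share moved between 24.3% and 87.9% with the processing. In the rest of the artery library, a cluster of 311 cells (10.1%) scored highest for endothelial markers, with CDH5 at 419 CPM. Its low depth (median 9526 UMIs), with no endothelial marker among its 10 leading genes, left it unnamed. The unnamed cells of primed (1.39%) and vein ECs (3.47%) were also in shallow clusters that scored highest for endothelial markers. The artery library further held a cluster of 177 mural-like cells (5.74%), which scored 0.536 for mural and 0.514 for lateral mesoderm markers. Its 10 leading genes held the lateral mesoderm marker HAND1 and no mural marker, so that the markers do not separate these classes here. In primed ECs 501 cells (20.4%) were lateral mesoderm-like, with no marker of that class among their 10 leading genes. None of the 3247 cells of the lateral mesoderm library took this class, since its clusters that scored highest for it stayed unnamed. In vein ECs 579 cells (13.8%) were mural-like, 58 (1.38%) blood-like and 86 (2.04%) cardiac-like at a median depth of 2268 UMIs, with HAND1 and TAGLN of other classes among the 10 leading genes. Some endothelial-like clusters had a marker of another class among their 10 leading genes within the library. They held 30.4% of kept cells in sorted artery, 17.5% in unsorted artery, 5.67% in primed and 14.9% in vein ECs. The variable genes used for clustering were chosen within each library, and the shares were not compared with each other.

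The day 3 branches, primed ECs and artery ECs, were then compared within endothelial-like cells, to see how far the primed state differed from the arterial state. Primed ECs had lower levels of artery genes, higher levels of vein genes and higher levels of cell cycle genes. CXCR4 was at 1.37 against 256 CPM (108-fold lower in primed ECs) and the arterial connexin gene GJA4 at 4.20 against 124 CPM. APLNR was at 165 CPM (Poisson interval 163 to 167) against 4.46 (4.08 to 4.88), and NR2F2 at 11.0 against 0.644 CPM. SOX17 was at 281 CPM in primed ECs and 496 in artery ECs.

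In the artery list 13 of 17 measured members were at least 2-fold lower in primed ECs and none at least 2-fold higher (median -2.80, percentile 0, random range -0.44 to 0.42). HES4 was at 1.95 against 31.8 CPM and GJA5 at 1.52 against 26.9 CPM. Without the genes picked for separating both artery libraries from the others, 8 members were at least 2-fold lower. In the vein list 6 of 10 were at least 2-fold higher and none at least 2-fold lower (median 1.85, percentile 100), with FLRT2 at 30.2 against 5.06 CPM and NT5E at 10.1 against 1.51 CPM. The vein median was 0.70 with a pseudocount of 10 CPM, where 3 members were 2-fold higher. ERK response genes went both ways (2 of 13 at least 2-fold higher, 3 at least 2-fold lower, median -0.04, percentile 52.6). DUSP5 was at 59.6 against 15.4 CPM and SPRY4 at 80.1 against 201 CPM. Notch targets were lower for 5 of 6 members (median -2.65), with DLL4 at 12.1 against 143 CPM. TGF-beta targets were lower for 4 of 7 (median -2.14), with PMEPA1 at 7.95 against 153 CPM. BMP targets were higher for 4 of 8 and lower for 1 (median 1.20, percentile 99.9), with ID1 at 392 against 58.7 CPM and SMAD7, which is also in the TGF-beta list, at 2.25 against 21.6 CPM.

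All 12 S phase genes were at least 2-fold higher in primed ECs (median 2.05, percentile 100), with RRM2 at 166 against 9.42 CPM, and 8 of 12 G2/M genes were (median 1.08), with MKI67 at 257 against 71.2 CPM. Glycolysis genes were higher for 8 of 9 (median 1.36), with LDHA at 212 against 38.3 CPM and PKM at 501 against 124 CPM. Among genes named by their fold, TOMM6 (226 CPM against 0 UMIs), NME2 (1058 against 5.65 CPM), EEF1G (999.8 against 8.20 CPM), PALM2AKAP2 (214 against 2.31 CPM), ATP6V0C (87.5 against 0.381 CPM), MRPS24 (116 against 0.826 CPM), CBS (95.7 against 0.798 CPM) and TRAPPC5 (111 against 1.73 CPM) were higher in primed ECs and belong to the set that separates both artery libraries from the others. The linker histone gene H1-5 (428 against 11.3 CPM) was higher too. Lower in primed ECs were ACSM3 (2.16 against 249 CPM), SLIT3 (2.60 against 272 CPM), NRG3 (8.88 against 647 CPM), CHST1 (1.32 against 108.5 CPM), NCKAP5 (4.05 against 213 CPM), SOX6 (35.0 against 1459 CPM), SLC45A4 (2.51 against 99.9 CPM), SORBS2 (19.7 against 589 CPM) and DCC (9.12 against 334 CPM), of which all but DCC belong to that set.

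The angiogenic tip list had a median of -0.78 (4 of 11 lower, ESM1 at 124 against 1706 CPM) and the extracellular matrix list of -0.72. Without the set, which shrinks such differences by construction, these were -0.55 and -0.49, both inside the random range. Hypoxia genes (-0.87) lay below percentile 1, and their median was -0.02 with no filter on low members. Early response genes had a median of 1.02 (4 of 5 higher, JUN at 151 against 59.6 CPM). Pluripotency (-0.50), lateral mesoderm (0.46), Wnt target (-0.47), blood (0.90), mural (0.31), epithelial (-0.93) and cholesterol synthesis (0.01) medians lay within the central 95% of random lists. The mural median turned to -0.86 over all kept cells and to -0.77 with 3 endothelial markers required per cell, both below the random range. The endothelial list, which set the cell class, had a median of -0.29. Another scaling shifted all log2 ratios by -0.14 to -0.17.

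The last step of the vein branch, vein ECs against primed ECs, was compared because the study concerns inhibition of VEGF and ERK signalling. The labels name no libraries that differ only in that inhibition, so the differences below cannot be assigned to it. Within endothelial-like cells, ERK response genes, Notch targets and cell cycle genes were lower in vein ECs, and vein genes were higher. SPRY4, an ERK-induced inhibitor of receptor signalling, was at 0.272 against 80.1 CPM (63.7-fold lower), SPRED2 at 0.461 against 89.3 CPM (61.8-fold) and DUSP6 at 0.847 against 102 CPM (55.9-fold). The scavenger receptor gene STAB2 was at 467 against 0.223 CPM (383-fold higher), FLRT2 at 1455 against 30.2 CPM (46.7-fold) and NR2F2 at 327 CPM (Poisson interval 324 to 330) against 11.0 (10.4 to 11.6). SOX17 was at 22.5 against 281 CPM.

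In the ERK response list 12 of 13 measured members were at least 2-fold lower and none at least 2-fold higher (median -2.60, percentile 0, random range -0.42 to 0.51), and ETV5 was at 0.219 against 35.2 CPM. In the vein list 9 of 12 were at least 2-fold higher and 1 at least 2-fold lower (median 2.46, percentile 100), with the transcription factor gene MAF at 237 against 21.6 CPM and APLNR at 307 against 165 CPM. In the artery list 5 of 14 were at least 2-fold lower and 2 at least 2-fold higher (median -0.57, percentile 0.37). HEY1 was at 2.88 against 123 CPM and DLL4 at 0.567 against 12.1 CPM, while GJA4 was at 48.1 against 4.20 CPM. Over all kept cells, 3 artery genes were at least 2-fold lower. Angiogenic tip genes had a median of -0.82 (3 of 9 lower, percentile 0.56), with APLN, the ligand of APLNR, at 2.43 against 94.5 CPM and ESM1 at 8.84 against 124 CPM. Scaled by the median of ratios, 5 tip genes were at least 2-fold lower. All 4 measured Notch targets were lower (median -2.47), and HEY1, HEY2 and DLL4 also stand in the artery list.

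All 12 S phase genes (median -2.42) and all 12 G2/M genes (median -2.87) were at least 2-fold lower in vein ECs, with RRM2 at 11.5 against 166 CPM and MKI67 at 15.3 against 257 CPM. Cholesterol synthesis genes were lower for 6 of 12 members (median -1.09), with INSIG1 at 27.7 against 89.1 CPM. Glycolysis genes were lower for 5 of 9 (median -1.04), with PFKP at 20.4 against 100.4 CPM. Wnt targets were higher for 4 of 7 (median 1.29, percentile 99.7), with LEF1 at 39.1 against 10.0 CPM and TNFRSF19 at 46.7 against 1.03 CPM. Further genes higher in vein ECs were IGF1 (316 against 1.23 CPM), the semaphorin gene SEMA3D (230 against 0.855 CPM), C12orf42 (479 against 0.454 CPM), SLC35F4 (113 against 0.171 CPM), PCSK2 (141 against 0.558 CPM), RGS7 (173 against 1.70 CPM), TMEM132C (78.4 against 0.669 CPM) and ZNF503 (58.2 against 0.469 CPM). Lower were H1-5 (9.27 against 428 CPM), PRDM1 (4.84 against 192 CPM), RFX8 (1.40 against 77.3 CPM), EMP1 (3.52 against 121 CPM) and EXOC3L2 (1.15 against 55.5 CPM).

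Early response genes had a median of -1.22 (3 of 5 lower, JUN at 15.9 against 151 CPM), which was -0.48 and inside the random range over all kept cells. The lateral mesoderm list (1.00) and the mural list (1.23) lay above percentile 99, and moved to 0.54 and 0.45, inside the random range, without endothelial-like clusters led by markers of another class. Pluripotency (0.56), BMP target (0.46), TGF-beta target (-0.45), blood (0.09), hypoxia (-0.42) and extracellular matrix (-0.12) medians lay within the central 95% of random lists. In the endothelial list, which set the class, the median was -0.14, with PLVAP at 14.2 against 218 CPM and CLDN5 at 401 against 48.4 CPM. Another scaling shifted all log2 ratios by 0.16 to 0.19.

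**Figure D2:**
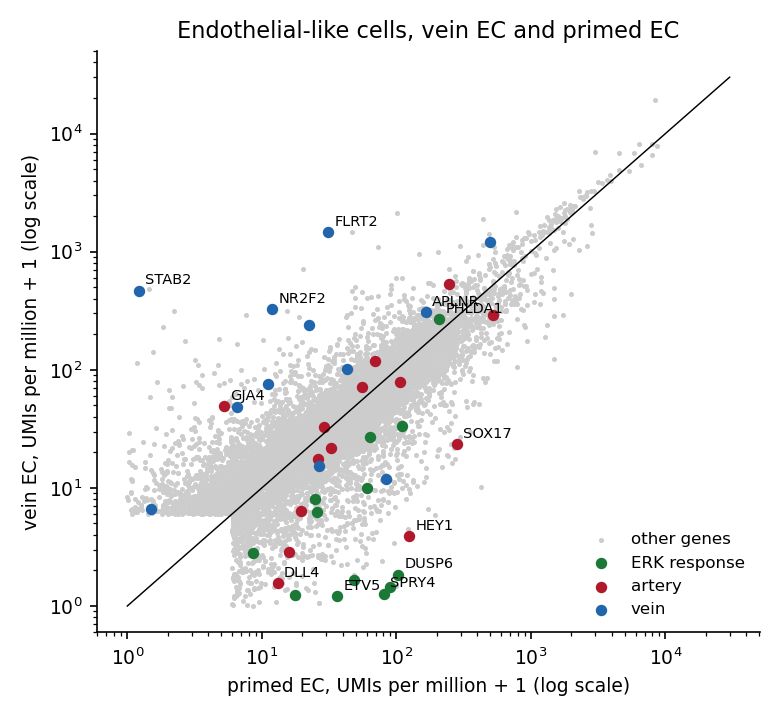
Levels in endothelial-like cells of vein ECs (vertical axis) and primed ECs (horizontal axis), in CPM plus 1 on log axes, 1 point per gene, with equality as the line. ERK response genes such as SPRY4 (0.272 against 80.1 CPM) lie below the line and vein genes such as STAB2 (467 against 0.223 CPM) above it, while the artery gene GJA4 (48.1 against 4.20 CPM) lies above it.

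The end products of the branches, vein ECs and artery ECs, were compared to describe how far they lay apart. Arterial and vein markers separated in opposite directions. STAB2 was at 467 CPM in vein ECs against 0.299 in artery ECs (360.1-fold higher), FLRT2 at 1455 against 5.06 CPM (240.2-fold) and NR2F2 at 327 against 0.644 CPM (199-fold). CXCR4 was at 0.0756 against 256 CPM (239-fold lower), ESM1 at 8.84 against 1706 CPM (173-fold) and HEY1 at 2.88 against 436 CPM (113-fold).

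In the artery list 15 of 17 members were at least 2-fold lower in vein ECs and none at least 2-fold higher (median -3.72, percentile 0), with DLL4 at 0.567 against 143 CPM and IGFBP3 at 1.89 against 117 CPM. In the vein list 9 of 12 were at least 2-fold higher and 1 at least 2-fold lower (median 4.28, percentile 100), with APLNR at 307 against 4.46 CPM. ERK response genes were lower for 9 of 12 (median -2.97), with SPRY4 at 0.272 against 201 CPM and SPRED2 at 0.461 against 181 CPM. All 6 Notch targets (median -4.07) and all 6 TGF-beta targets (median -2.03) were at least 2-fold lower, and BMP targets were higher for 5 of 8 (median 1.56), with ID2 at 114 against 9.98 CPM. Angiogenic tip genes were lower for 9 of 11 (median -1.47) and G2/M genes for 9 of 12 (median -1.78). S phase genes had a median of -0.38 at percentile 2.40, the edge of the random range, and 0.14 over all kept cells.

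Among the other genes named by their fold, TOMM6 (168 CPM against 0 UMIs), EEF1G (1222 against 8.20 CPM), NME2 (660.1 against 5.65 CPM), CHN2 (119 against 0.417 CPM) and ANGPT1 (136 against 0.308 CPM) were higher in vein ECs, and SLIT3 (1.13 against 272 CPM), RP1 (2.71 against 455 CPM), KCNQ3 (0.159 against 106 CPM) and CHST1 (0.25 against 108.5 CPM) were lower. These, CXCR4, ESM1 and DLL4 belong to the set that separates both artery libraries from the others. IGF1 (316 against 1.36 CPM) and SEMA3D (230 against 0.826 CPM) were also higher. Wnt targets (1.10), lateral mesoderm (2.02) and mural genes (1.24) lay above percentile 99. With no filter on low members the Wnt median was 0.35, with 3 endothelial markers required per cell the lateral mesoderm median was 0.59, and without clusters led by another class the mural median was 0.45. Each of these lay inside the random range. Cholesterol synthesis genes had a median of -1.09 (-0.53 over all kept cells), pluripotency genes of -0.95 (-0.38 over all kept cells), hypoxia genes of -0.83 (0.05 over all kept cells) and extracellular matrix genes of -0.76 (-0.65 without the set). All 4 lay below the random range, and each value in parentheses lay inside it. Glycolysis (0.45), epithelial (-0.53), early response (-0.54) and endothelial (-0.38) medians lay within the central 95% of random lists.

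**Figure D3:**
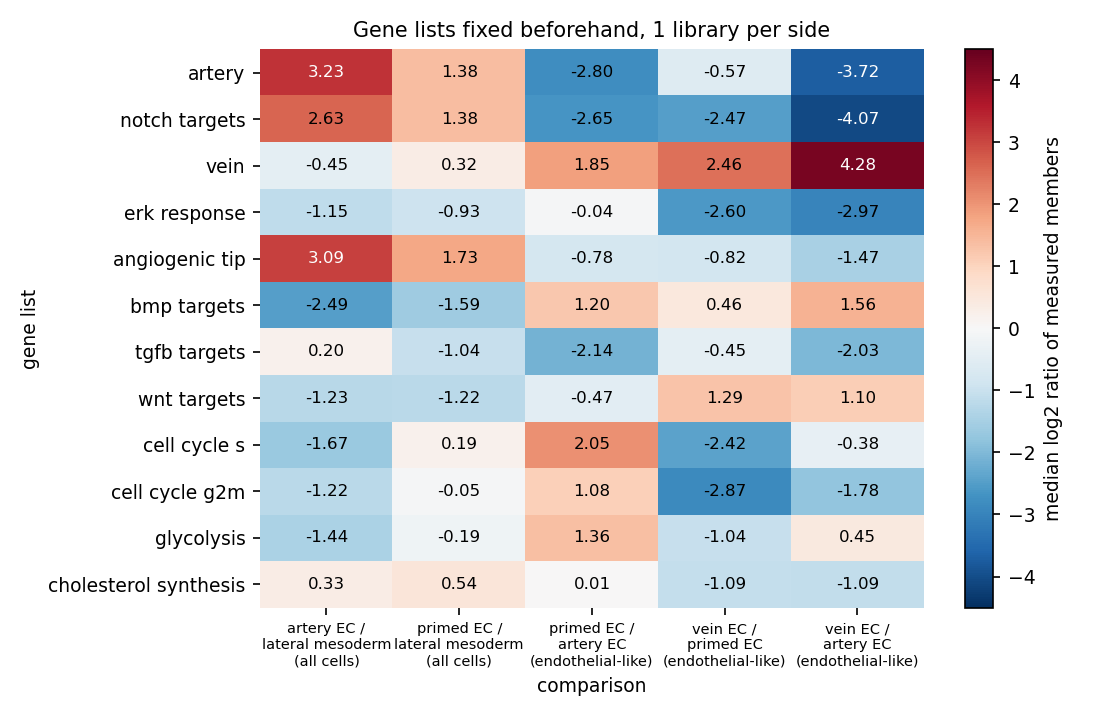
Median log2 ratio of the measured members of 12 gene lists (rows) in 5 comparisons (columns), 1 library per side, with red for higher and blue for lower in the first-named library. The vein list had medians of 1.85, 2.46 and 4.28 in the 3 comparisons of endothelial-like cells, and the ERK response list had -0.04, -2.60 and -2.97.

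Detection of SOX17 and APLNR in the same cells was measured in endothelial-like cells thinned to 10000 UMIs each, to ask whether these genes were detected together in primed ECs. Both were detected in 51.0% of primed EC cells (966 of 1894, exact 95% binomial interval 48.7 to 53.3), in 2.83% of artery EC cells (71 of 2509, 2.22 to 3.56) and in 16.4% of vein EC cells (519 of 3157, 15.2 to 17.8). In primed ECs SOX17 was detected in 75.7% and APLNR in 68.6% of cells, so that 51.9% would hold both if detection were independent. In artery ECs SOX17 was detected in 97.3% and APLNR in 3.03% of cells, and in vein ECs SOX17 in 18.8% and APLNR in 85.9%. As a background, of lateral mesoderm-like cells in the primed EC library 1.45% held both (7 of 483, 0.585 to 2.96), at a median depth of 54812 UMIs against 60980 in its endothelial-like cells. Of mural-like cells in the vein EC library none of 551 did (exact 95% upper limit 0.667%), at 68189 against 36093 UMIs. Of mural-like cells in the artery EC library 6.85% did (10 of 146, 3.33 to 12.2), against 2.83% of artery EC cells. SOX17 was detected in 17.8% and APLNR in 41.1% of these mural-like cells, so they give no background for artery ECs. APLNR was also detected in 22.4% of the lateral mesoderm-like primed cells and in 28.3% of the mural-like vein cells, which limits those backgrounds too. In the earlier endothelial-like cells of lateral mesoderm the share with both was 14.99% (168 of 1121, 12.9 to 17.2). APLNR was already detected in 85.1% of those cells, so its detection in primed ECs is no gain of a vein gene. NR2F2, the other vein-associated gene read in every library, was detected in 9.03% of primed and 86.3% of vein EC cells. It was also detected in 28.4% of lateral mesoderm-like cells of the primed library and in 75.3% of mural-like cells of the vein library. Frequent detection of NR2F2 in the vein library was thus not particular to endothelial-like cells. Thinning left out 86 artery, 23 primed and 182 vein EC cells with fewer UMIs. Without thinning the shares were 7.28% in artery, 86.0% in primed and 39.1% in vein ECs.

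**Figure D4:**
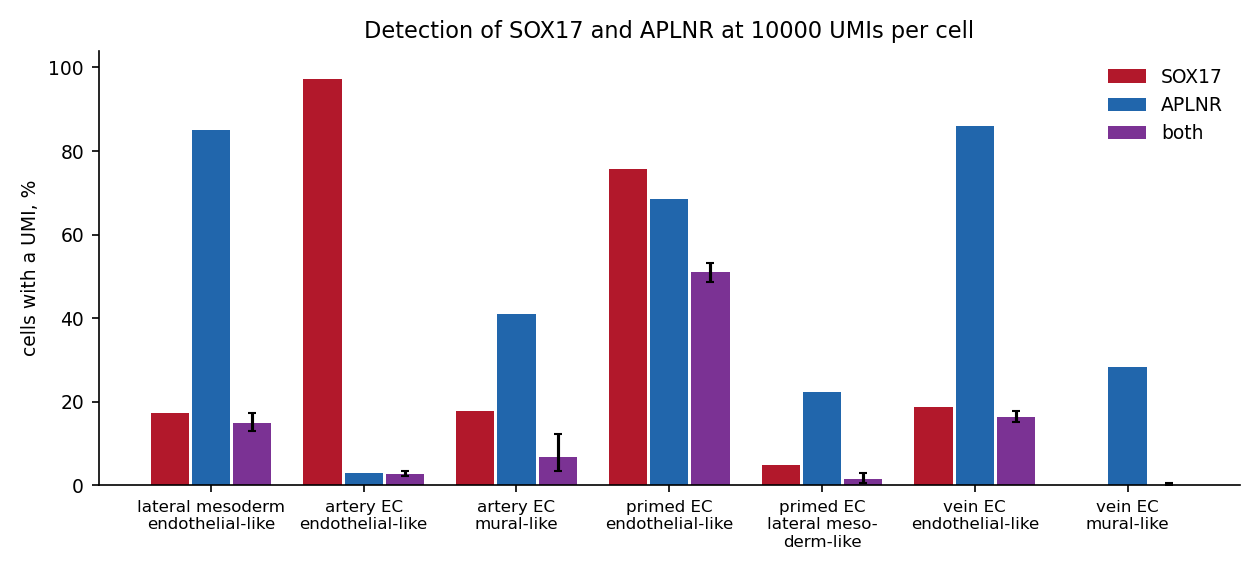
Percent of cells with at least 1 UMI of SOX17, of APLNR and of both after thinning each cell to 10000 UMIs, in endothelial-like cells of 4 libraries and in 3 populations of other cells from them. Error bars on the share with both are exact 95% binomial intervals (counting error only), and this share was 51.0% in primed ECs, 2.83% in artery ECs, 16.4% in vein ECs and 14.99% in lateral mesoderm.

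The sorted and unsorted artery EC libraries were compared to describe what the CD144 gate may have removed. Whether they share a culture or a day is not known, so such a difference cannot be told apart from the gate. Genes of mural cells and lateral mesoderm were lower in the sorted library, and artery genes were at similar levels. The cardiac actin gene ACTC1 was at 0.636 CPM in sorted against 323 in unsorted cells (198-fold lower), the netrin receptor gene UNC5C at 2.12 against 81.4 CPM (26.4-fold), ALCAM at 4.34 against 61.6 CPM (11.7-fold) and TAGLN, a smooth muscle gene, at 35.7 against 144 CPM (3.96-fold). CDH5 encodes the sorted antigen, and its level is no finding here.

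In the mural list 5 of 8 members were at least 2-fold lower and none at least 2-fold higher (median -1.74, percentile 0), with COL1A1 at 7.94 against 42.2 CPM and COL3A1 at 0.0763 against 13.3 CPM. Lateral mesoderm genes were lower for 5 of 9 (median -1.61, percentile 0), with HAND1 at 0.17 against 20.1 CPM, and BMP targets for 3 of 8 (median -0.27), with BAMBI at 15.2 against 54.1 CPM. Within endothelial-like cells only, an alternative chosen after seeing the data, the mural median was -0.17 with 0 members 2-fold lower, and the lateral mesoderm and BMP medians turned to 0.06 and 0.04. The endothelial list had a median of 0.18 (percentile 100) and the artery list of 0.10 (percentile 94.1), with no member of either 2-fold apart. In the vein list FLRT2 was at 2.57 against 32.6 CPM and APLNR at 2.87 against 8.95 CPM, at a median of 0.06. The genes highest in the sorted library by fold were OOEP (84.2 against 36.7 CPM, 2.26-fold), STEAP1B (134 against 62.2 CPM, 2.14-fold), SLC27A4 (85.9 against 40.4 CPM, 2.10-fold) and TXNDC5 (89.8 against 46.4 CPM, 1.92-fold). PLEKHA7, HNRNPA1L3, EFNA1, APLN, FUT11 and PLPP3 followed at 1.73-fold to 1.32-fold. SPP1 (6.29 against 55.8 CPM), PCDH7 (15.4 against 93.6 CPM), KIF26B (31.1 against 121 CPM), MLLT3 (41.8 against 140 CPM) and ARF5 (20.9 against 66.3 CPM) were lower. G2/M genes had a median of -0.16, below the central 95% of random lists, and S phase genes of -0.02. With the mean over cells of CPM the G2/M median was -0.045, inside the random range. The remaining 12 lists with at least 3 measured members had medians from -0.13 to 0.12. Among them Notch targets and glycolysis genes lay below the central 95% of random lists and cholesterol synthesis genes above it, and each entered the random range under other settings.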

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

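No test was run on the result of this part. A cluster of 58 blood-like cells, 1.38% of the kept vein EC cells (exact 95% binomial interval 1.05 to 1.78), lay outside every comparison of endothelial-like cells. It was picked for lying above 0.0713%, the share that 3 cells would make, a mark that any cluster of more than 3 cells passes. It was led by the red cell surface genes GYPE, GYPB, KEL and RHAG and by ITGB3, an integrin of platelets. It held RUNX1 at 971 CPM, GATA1 at 89.8 CPM and the embryonic globin gene HBE1 at 73.8 CPM. CDH5 was at 24.9 CPM in this cluster, against 277 CPM in the endothelial-like cells of the library.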

How the results depend on the processing

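With 1 library per group no library could be left out of a group. Comparisons with the sorted artery library in place of the unsorted library, or with the sorted primed and vein libraries, were not run. No paired analysis across sorted and unsorted libraries was made, and no test was made. All 181 alternative values of the 17 list medians of interest kept their side of the random range. All kept their direction except the ERK response median of primed against artery ECs, which ran from -0.14 to 0.31 inside that range. In vein against primed ECs the ERK response median ran from -2.77 to -1.49 and the vein median from 1.28 to 2.59. In primed against artery ECs the artery median ran from -2.83 to -1.83 and the vein median from 0.70 to 2.01, and in vein against artery ECs they ran from -3.81 to -2.18 and from 2.99 to 4.47. Of the other list medians 1298 values stayed the same, 23 left the random range, 49 entered it and 6 that stood apart changed sign. Of single genes 4748 stayed within their interval, 2116 moved and 11 were reversed. The causes below were not tested, except where fewer UMIs, members or cells enter by construction.

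Sign changes of values that stood apart, as log2 ratios, were as follows. With no filter on low members the blood median of lateral mesoderm against primitive streak was -0.0030. In vein against primed ECs, the rule of 3 markers per cell gave -0.15 for HAND2 and 0.34 for TAGLN, all kept cells gave 1.38 for ATF3, -0.057 for ID2 and 2.14 for TAGLN, and leaving out clusters led by another class gave -0.34 for HAND2. In vein against artery ECs, all kept cells gave 0.14 for S phase, 0.053 for hypoxia, 0.74 for SLC2A1 and 0.021 for PFKP, and leaving out those clusters gave -0.44 for COL1A1. In sorted against unsorted artery ECs, the mean over cells gave 0.022 for glycolysis, and endothelial-like cells alone gave 0.064 for lateral mesoderm, 0.041 for BMP targets, 0.39 for ID2 and 0.0215 for TNFRSF19. The mural median of primed against artery ECs, 0.31 and inside the random range, turned to -0.77 with 3 markers per cell and to -0.86 over all kept cells, both below it. The other medians that left the range kept their sign. They were mural and paraxial mesoderm in primed ECs against lateral mesoderm, pluripotency, blood and lateral mesoderm in primed against artery ECs, TGF-beta targets and endothelial in vein against primed ECs, early response, endothelial and glycolysis in vein against artery ECs, Notch targets in lateral mesoderm, cardiac in artery ECs against lateral mesoderm, and tip, Wnt and artery genes in sorted artery ECs.

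The share of endothelial-like cells moved with the rule of 3 markers per cell, to 1.15% in primitive streak, 87.9% in lateral mesoderm, 98.1% in unsorted artery, 87.7% in primed and 87.5% in vein ECs. Lateral mesoderm gave 24.3% with no doublet removal and 29.01% at resolution 1. With no filter on cells it was 97.46% in sorted artery, 66.2% in unsorted artery, 73.1% in primed and 60.9% in vein ECs, and with the stricter filter 89.0% in unsorted artery and 82.2% in vein ECs. Without clusters led by another class it was 69.6% in sorted artery, 66.7% in unsorted artery, 72.5% in primed and 64.4% in vein ECs. The share with SOX17 and APLNR was 7.28% in artery, 86.0% in primed and 39.1% in vein ECs without thinning, and 0.917%, 23.1% and 3.39% with 2 UMIs of each. Over all kept cells it was 40.8% in primed and 13.8% in vein ECs, and without clusters led by another class 54.0% and 18.1%. Under each of these settings it was highest in primed and lowest in artery ECs where all 3 were measured.

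Counts of list members 2-fold apart moved in 9 of 181 values. In primed against artery ECs, ERK response genes lower went from 3 to 1 with the median of ratios, with 3 markers per cell and over all kept cells, vein genes higher from 6 to 3 with a pseudocount of 10 CPM, and artery genes lower from 13 to 8 without the genes that separate the artery libraries, which were picked by that difference. In vein against primed ECs, tip genes lower went from 3 to 5 with the median of ratios and artery genes lower from 5 to 3 over all kept cells. In sorted against unsorted artery ECs, mural genes lower went from 5 to 3 with a pseudocount of 10 CPM and to 0 in endothelial-like cells.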

Other observations

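Of the tests in this part, those of genes higher in artery libraries, of SOX17 with APLNR and of the levels that artery ECs would bring with GJA4 were chosen after the results were seen, as were the clusters described. Within primed ECs a cluster of 139 endothelial-like cells was led by the blood transcription factor genes RUNX1 and GFI1B together with TFPI2 and CD44. RUNX1 was at 369 CPM there, against 25.9 to 39.3 CPM in the other endothelial-like clusters of the library, while CDH5 was at 261 CPM and SOX17 at 59.6 CPM. SOX17 and APLNR were both detected in 12.9% of its cells after thinning (18 of 139, exact 95% binomial interval 7.86 to 19.7), and in 51.4% to 57.1% of cells in the other 5 endothelial-like clusters. In vein ECs a cluster of 49 endothelial-like cells held RUNX1 at 1168 CPM with CDH5 at 212 CPM, and was led by KCND2 and the myeloid transcription factor gene CEBPA.

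Vein ECs held further clusters that differed in vein and cell cycle genes. The largest, of 1507 cells, was led by NEFH, C12orf42, NCAM2 and STAB2, with NR2F2 at 374 CPM and SOX17 at 12.7 CPM. Another, of 943 cells, was led by TM4SF18, CCND1 and ADGRF5, with NR2F2 at 253 CPM, SOX17 at 42.4 CPM and APLNR at 428 CPM. MKI67 was at 4.49 and 4.03 CPM in these clusters and at 370 CPM in a cluster of 75 cells. In unsorted artery ECs a cluster of 25 cells had APLNR at 175 CPM beside SOX17 at 297 CPM, and 54.2% of its 24 cells deep enough for thinning held both (32.8 to 74.4).

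Genes that separate both artery libraries from the other 4 were weighed against the difference in gene lists. Of 150 genes lower in both, 75.3% (67.6 to 82.0) overlapped another gene of the same strand, 7.69 times the 9.80% of genes of like expression, which is consistent with reads lost to overlapping genes of the shorter list. Of 125 genes higher in both, such as ESM1, CXCR4 and MECOM, 6.40% overlapped another gene. Within the unsorted artery library their median log2 ratio of endothelial-like over mural-like cells, which scored nearly as high for lateral mesoderm, was 2.83 (bootstrap interval 2.34 to 3.03), and 105 of them were at least 2-fold higher in endothelial-like cells. Most of the set thus also differs between cells counted on the same list. A list effect alike in every cell would leave this ratio unchanged, so the ratio does not exclude such an effect. The set was also picked as high in libraries of mostly endothelial-like cells, which favours such ratios. An effect of the list stays open for every gene of the set, ESM1, CXCR4 and MECOM included. A ratio of at most 0.5 was seen in 19 genes, among them PTP4A1 at -0.56 and CHTF8 at 0.19. A batch difference between the artery and the other libraries cannot be told apart from the artery state.

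Detection of SOX17 with APLNR in primed ECs may reflect cells that express both. A mixture of cells with SOX17 alone and cells with APLNR alone would hold both only through free RNA or doublets. APLNR, the more often detected of the genes in lateral mesoderm-like cells of the library, had an upper limit of 26.3% there. With 3 times the assumed doublet share added, such a mixture allows at most 32.9% of cells with both, below the lower limit of 48.7% observed. The shares with each gene decide this alone, since SOX17 in 75.7% and APLNR in 68.6% of cells leave at least 44.3% with both. A mixture that includes cells with both genes was not tested. Doublets were assumed at 2.2% of barcodes, against 51.0% of cells with both. Free RNA would give the other cells of the library a like share, and lateral mesoderm-like cells had 1.45%. None of these explanations alone reaches the share, and whether it marks a step toward vein cells was not tested.

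GJA4, an arterial connexin gene, was higher in vein than in primed ECs (48.1 against 4.20 CPM), while HEY1, SOX17 and DLL4 were lower. Artery-like cells left in the vein library could bring GJA4, and would bring the other artery genes with it. Vein EC cells with a GJA4 UMI (1323) held the 10 other measured artery genes at a median log2 ratio of 0.61 (bootstrap interval -0.18 to 0.85) over the 2016 without, below the bound of 1 set in advance against that explanation, a split that would dilute a small group of artery-like cells. To give the GJA4 level, 36.6% of the cells would have to be like artery ECs, which held 124 CPM over all their endothelial-like cells. Artery cells with more GJA4 would need a smaller share, such as a cluster of 344 cells with GJA4 among its leading genes. Such cells were not tested as a source. The 16 other artery genes stood at a median log2 ratio of -2.42 (bootstrap interval -3.38 to -0.62) over the levels the 36.6% share would bring, with CXCR4 at 0.0756 against 93.5 CPM and HEY1 at 2.88 against 159 CPM. Over the 11 genes that do not separate the artery libraries it was -2.35 (-2.83 to 0.089), an interval that includes equality and so does not meet the bound set against this explanation. GJA4 was at 266 CPM in a vein cluster of 187 cells with NR2F2 at 333 CPM, and at 183 CPM in another of 171 cells with NR2F2 at 356 CPM. Both lay above its level over all endothelial-like artery ECs, and single artery clusters were not compared. If all cells of these clusters were like artery ECs, artery EC levels would be needed, and the 16 genes stood at medians of -3.41 (-4.49 to -1.31) and -4.22 (-4.88 to -1.40) over them. These medians lay below what artery ECs at their mean levels would bring, but genes that separate the artery libraries, such as CXCR4, lower them by construction. They do not exclude artery ECs as the source of the level. Only the split by a GJA4 UMI bears on artery-like cells of another kind. The hypothesis that vein-like cells themselves express GJA4 remains open, since it was found and examined in the same library.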
